A study of Arabidopsis thaliana with 6 samples.

How the data were processed

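The series holds 6 arrays of Arabidopsis thaliana embryos at the 16-cell stage, 3 of nuclear and 3 of cellular RNA. Per the labels' protocols, plants grew at 22 °C with 16 h of light and 8 h of dark, RNA was taken with TRIzol, and 4.25 ug of biotinylated cDNA per array was made by whole-transcriptome amplification. Groups and replicate numbers were read from the sample titles, which call the samples biological replicates. The nuclear and cellular samples differ in how they were isolated as well as in the RNA they hold, so isolation method and RNA compartment cannot be separated in this design.

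The deposited intensity values were made by the authors with RMA, per the submitters' processing notes. Its version, the array type and the probe set definitions were not given in the sources used here. RMA was run before the table was deposited, and, since RMA as usually run gives all arrays the same probe distribution, it can move changes between RNA pools of different make-up. The deposited table is on a linear scale, so log2 was taken once, with no second normalization and no filter on dim genes. There are no detection calls. Array medians lay between 2.47 and 2.68 on the log2 scale, and a fold against a group near or below them is compressed. The table holds 27826 rows, one per locus. No genome build is named, so no coordinates are given. Loci were named through a RefSeq gene table of assembly TAIR10.1, which matched 27241 rows. The 585 others, 14 chloroplast, 92 mitochondrial and 479 nuclear-chromosome loci, were left out, as fixed before the data were examined. They were first kept in by mistake and then left out after both sets of counts were known, and the fit over all rows is given as an alternative. In 83 sets, 172 rows share all 6 values with another row, which leaves overlapping or near-identical loci uncertain.

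Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 4 residual and 2.33 prior degrees of freedom), with nuclear minus cellular as the contrast and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 25 gene lists or list rules were fixed before the data were examined. Of these, 20 had at least 5 matched genes and were tested with camera at a preset inter-gene correlation of 0.01, 2 organelle lists were tested over all rows, 1 held a single gene, and 2 that need exon counts were not analysed here. The ribosomal and respiratory chain lists were built from gene symbols and synonyms. They hold only genes whose names carry the words searched for, and may cover only part of each class. Of the ribosomal genes, 11 organellar proteins whose synonyms do not name the organelle were moved by hand to the organellar list before any change was computed. Of the 20 lists, 13 passed the threshold, 6 higher and 7 lower, and 0 passed with an estimated correlation. List changes are also given relative to the median of all genes.

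The genes named are, by a rule fixed before the data were examined, the 12 largest rises and 12 largest falls past the threshold with non-overlapping arrays and a higher group mean above the median of all values. The rule adds for each list its 2 largest rises and 2 largest falls past the threshold, or the 2 lowest p where none passed, as well as RANGAP1 and genes counted as 5 or fewer, which were known only after their values were seen. ATMG00920, ATMG00810, ATCG00970, ATCG01160 and ATCG00240 come from the fit over all rows. Lists of Calvin cycle, further seed coat and vascular or guard cell genes were written later, before their values were seen.

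The test was checked on simulated data: 27241 genes with the real means and spreads, 200 of them changed between nuclear and cellular arrays. Of 50 genes per size it recovered 3 at a log2 change of 1, 25 at 2, 36 at 3 and 39 at 4, and 4.63% of calls were false. Both lists shifted by 1 were recovered and 0 of the unchanged lists were called. The simulated genes were drawn independently of each other, while the real cell cycle list had an estimated inter-gene correlation of 0.518. The check therefore cannot show how the list test behaves where the genes of a list vary together. It changed 200 genes, while the real comparison called 1597, and the adjusted threshold depends on how many genes change. The recovered counts thus do not give the sensitivity of the real test. The share of false calls holds only for arrays without shared shifts. Alternatives were cyclic loess, centring on protein-coding genes, 2 filters on dim genes, a trended robust variance, array weights, a replicate block, all rows, a 1.5-fold limit, each array left out in turn and 3 other list tests: camera with an estimated correlation, camera on ranks and fry. Camera compares the genes of a list with all other genes, while fry asks whether they move one way on balance and makes no such comparison, so ranges of adjusted p for lists cover camera alone. Quantile normalization of gene values, identical rows counted once, organelle rows shared with the nuclear chromosomes left out and the ribosomal lists by rule alone were added after seeing the data.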

Results

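RNA was measured on 6 microarrays in whole embryos of Arabidopsis thaliana at the 16-cell stage, collected 72 h after hand pollination. On 3 arrays the RNA came from nuclei captured with INTACT, in which a tagged nuclear envelope protein is biotinylated in the chosen cells so that their nuclei can be pulled down. On the other 3 arrays it was cellular RNA from embryos dissected with a micromanipulator. The labels call the 3 samples of each group biological replicates. The question was how the nuclear profile of an embryo compares with that of its whole cells, so each gene was compared as nuclear minus cellular. The table has no detection calls, and the number of arrays, 3 per group, limits the precision.

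Of the gene lists fixed before the data were examined, those of the cell cycle (20 of 40 genes fell), cytosolic ribosomal proteins (16 of 37 fell) and embryo patterning (12 of 40 fell) were lower in nuclear than in cellular RNA, while those of photosynthesis (16 of 39 rose) and early wound response (6 of 23 rose) were higher. The list of seed coat markers, of a tissue around the embryo, was also higher, with 20 of 20 genes above 0 but 0 called singly. These list calls came from camera with a preset inter-gene correlation, and of 20 lists tested 13 passed with it and 0 with an estimated correlation (3 at an unadjusted p under 0.05). Of the 13 lists, 9 passed under every other camera alternative, with adjusted p up to 0.0307, that of long non-coding and antisense genes. Of 27241 genes tested, 313 were higher and 1284 were lower in nuclear RNA (limma, two-sided, Benjamini-Hochberg adjusted p under 0.05), and 297 and 1273 of these differed at least 2-fold. The median called rise was 2.03 and the median called fall was -2.33 on the log2 scale. At least 10-fold changes were called for 41 higher and 227 lower genes. The arrays of the groups did not overlap for 33.0% of genes, against 10% by chance, and of these more had all nuclear arrays above (5071) than below (3928) the cellular ones, unlike the calls. The median log2 change of all genes was 0.13, and cyclic loess between arrays, which took it to 0.02, gave 489 higher and 846 lower genes. Lower genes thus made up 80.4% of calls as deposited, 63.4% after cyclic loess and 68.5% after quantile normalization, an alternative chosen after seeing the data. With fewer arrays the counts moved: leaving out nuclear replicate 2 left 188 higher and 622 lower genes, leaving out cellular replicate 1 left 54 and 436, leaving out cellular replicate 2 left 28 and 254, and leaving out nuclear replicate 1 left 225 and 828. Without cellular replicate 3, which lay nearest the nuclear arrays, 419 were higher and 1688 lower.

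The largest rise was that of RBCS1B (AT5G38430), a small subunit of the carbon-fixing enzyme Rubisco with near-identical copies in the genome, which was 34.9-fold higher in nuclear RNA (log2 change 5.13, SE 0.99, adjusted p = 0.0372). LOX4 (AT1G72520) and LOX2 (AT3G45140), lipoxygenases that start jasmonate synthesis, had log2 changes of 4.58 and 4.14. SYP121, a syntaxin of secretion at the plasma membrane, was 23.0-fold higher and FLA12, a fasciclin-like arabinogalactan protein, was 21.6-fold higher. TGG2, a myrosinase of glucosinolate breakdown, had a log2 change of 4.18. NPR3, a salicylic acid receptor, rose 17.0-fold, and LYK5, a receptor kinase of chitin sensing, 16.5-fold. The other large rises were of AT4G02000 (26.6-fold), AT1G17200 (22.0-fold), AT3G27540 (20.7-fold) and AT1G15010 (18.3-fold). Adjusted p for these 12 genes lay between 0.00255 for AT3G27540 and 0.0383 for AT1G17200. Only AT4G02000 and AT3G27540 passed under every alternative but the 1.5-fold limit, under which genes were counted and not followed singly. The other 10 each lost the call when a single array was left out (adjusted p up to 0.143): 10 without cellular replicate 2, 8 without cellular replicate 1, 5 without nuclear replicate 2, 3 each without nuclear replicates 1 and 3, and 1 without cellular replicate 3.

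The largest fall was that of AT5G61412, 128-fold lower in nuclear RNA (log2 change -6.99, SE 0.88, adjusted p = 0.0121). HIK (AT1G18370), a kinesin needed for cytokinesis, was 37.9-fold lower (log2 change -5.24, SE 0.21, adjusted p = 0.00245). NSN1, a nucleolar GTPase, was 43.4-fold lower, and CYP78A5, a cytochrome P450 that promotes organ growth, was 41.6-fold lower. AT1G04645 was 61.9-fold lower, AT4G00390 58.3-fold, AT4G33145 53.1-fold and AT5G08460 45.4-fold. AT5G62440 was 43.8-fold lower, AT5G63085 42.5-fold, AT1G60640 39.4-fold and AT1G04880 37.7-fold. The nuclear means of these 12 genes lay between 2.16 for HIK and 3.86 for CYP78A5 on the log2 scale, against array medians of 2.47 to 2.68, and a fold against so dim a level is compressed. Of the 12, 10 passed under every alternative but the 1.5-fold limit, where single genes were not followed. AT5G61412 lost the call without cellular replicate 1 (adjusted p = 0.0508), and AT5G61412 and CYP78A5 lost it without cellular replicate 2 (adjusted p up to 0.0615).

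**Figure D1:**
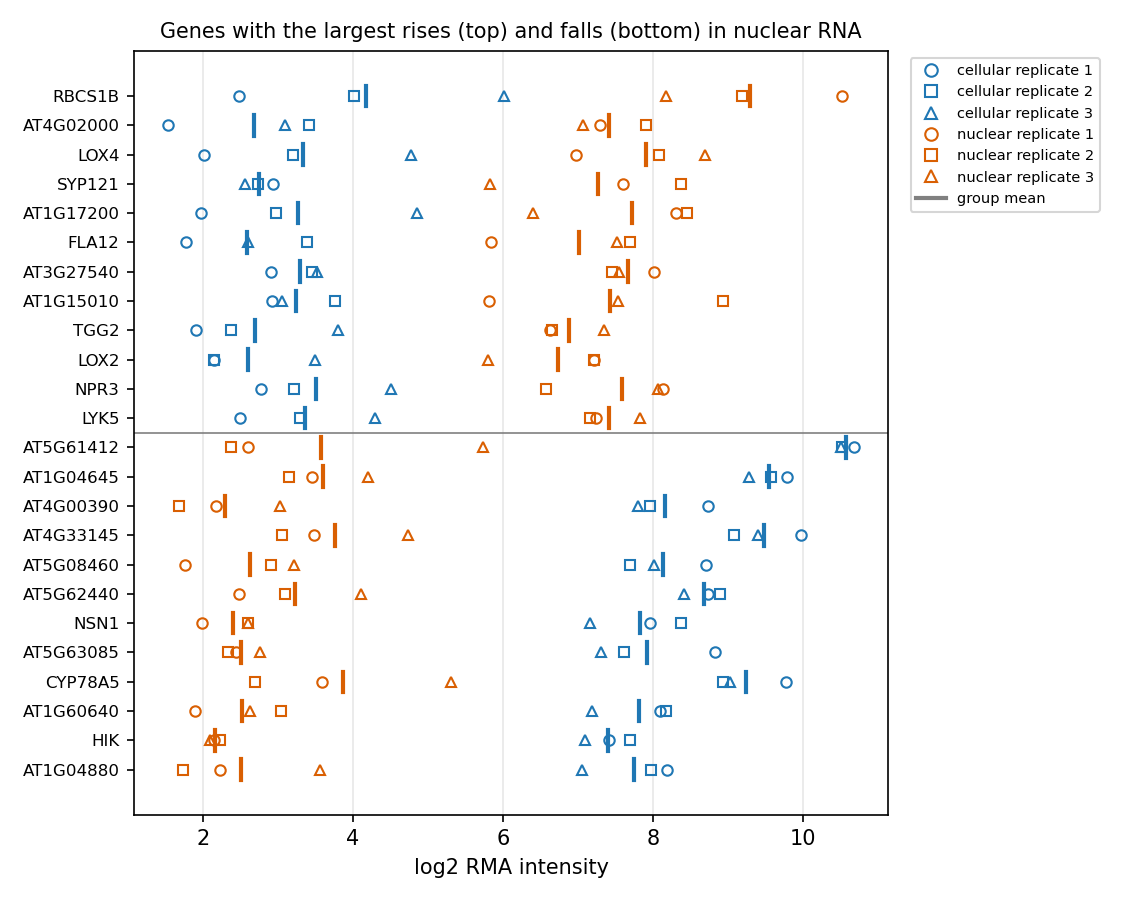
Log2 RMA intensity on each of the 6 arrays for the 12 genes with the largest rises (top) and the 12 with the largest falls (bottom) in nuclear RNA. Symbols are arrays, shaped by replicate number and coloured by group, vertical bars are group means (n = 3), and the groups do not overlap for any gene shown, with means of 9.30 and 4.17 for RBCS1B.

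Among the lists, genes of the cell cycle and DNA replication were the furthest below the rest. Of 40 measured, 20 fell and 0 rose (32 fell when adjusted over the list alone), with a median log2 change of -2.60, or -2.73 relative to all genes (camera adjusted p = 3.52e-23; adjusted p = 0.167 with an estimated correlation). Besides HIK, the largest fall was that of CYCB1;4, a mitotic cyclin, at 24.7-fold (SE 0.48 on the log2 scale, adjusted p = 0.00797). Random lists matched on the cellular mean of the cell cycle genes had a median of -0.71 and a 5th percentile of -1.15. Part of the distance to all genes was thus shared by genes of that level. Such lists were not drawn for the nuclear minus cellular change of the histone, embryo patterning, DNA methylation and SR lists. Core and linker histone genes fell in 13 of 41 cases and rose in 0 (27 fell when adjusted over the list alone), with a median of -1.43, or -1.57 relative to all genes (camera adjusted p = 1.28e-15; adjusted p = 0.134 with an estimated correlation). HTA8, an H2A gene, was 15.1-fold lower and AT3G53650, an H2B gene, 14.2-fold lower. On the same arrays the median of 20 seed coat marker genes ran the other way: it was 6.63, 5.62 and 5.69 on nuclear replicates 1 to 3 and 3.09, 4.29 and 5.11 on cellular replicates 1 to 3. The cell cycle median was 3.07, 2.74 and 2.96 on the nuclear arrays and 6.70, 6.24 and 5.10 on the cellular arrays.

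Cytosolic ribosomal protein genes fell in 16 of 37 cases and rose in 0 (32 fell when adjusted over the list alone), and all 37 lay below 0, with a median of -1.76, or -1.89 relative to all genes (camera adjusted p = 2.97e-20; adjusted p = 0.131 with an estimated correlation). RPL10B was 12.2-fold lower (SE 0.56, adjusted p = 0.0211) and RPL23AB 10.1-fold lower (SE 0.22, adjusted p = 0.00360). The list's median was 6.90, 6.45 and 6.45 on the nuclear arrays and 8.90, 8.76 and 8.36 on cellular replicates 1 to 3, where the seed coat list, at 3.09, 4.29 and 5.11, was highest in replicate 3. Among translation elongation and initiation factors 2 of 17 fell and 0 rose (4 fell when adjusted over the list alone): AT5G19510, 5.63-fold, and AT1G07930, 2.35-fold. Both calls were lost after cyclic loess, and that of AT1G07930 also after quantile normalization and with the trended robust variance. Their median was -0.46, or -0.59 relative to all genes, and turned to 0.07 after cyclic loess (camera adjusted p = 0.00104 as deposited; adjusted p = 0.134 with an estimated correlation). Among 10000 random lists matched on the cellular mean the ribosomal median lay at the 1.25th percentile and the translation factor median at the 84.57th, where the random median was -0.88. The median of 21 genes named EIF, translation initiation factors grouped after the results were seen and sharing 2 genes with that list, lay at the 0.77th percentile. The call of the translation factors was lost after cyclic loess (adjusted p = 0.751), after quantile normalization (adjusted p = 0.286) and over the brighter genes (adjusted p = 0.153). Its adjusted p lay between 8.97e-04 and 0.751 over all camera alternatives, these included. Nuclear-encoded ribosomal proteins of plastids and mitochondria did not pass as a list, with 2 falls and 0 rises in 30 (1 rise and 4 falls when adjusted over the list alone), namely MRPL11 (5.37-fold) and RPL9 (4.61-fold), whose call was lost after cyclic loess and quantile normalization. Their median was -0.06 (camera adjusted p = 0.223), which became 0.35 after cyclic loess, 0.28 after quantile normalization, 0.09 without nuclear replicate 3, 0.02 without cellular replicate 1, -0.13 without cellular replicate 2 and -0.12 without cellular replicate 3.

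Embryo transcription factors and patterning genes were lower in 12 of 40 cases and higher in 1 (21 fell and 2 rose when adjusted over the list alone). Their median was -1.23, or -1.36 relative to all genes (camera adjusted p = 1.28e-08; adjusted p = 0.167 with an estimated correlation). WOX2, a homeobox gene of the apical embryo lineage, was 30.0-fold lower (log2 change -4.91, SE 0.68, adjusted p = 0.0150), and ESR1, an AP2-type regulator of embryo patterning, was 20.0-fold lower (SE 0.57, adjusted p = 0.0138). The 1 rise was that of SHR, a regulator of root radial pattern, at 2.15-fold (SE 0.22, adjusted p = 0.0426), a call lost over the brighter genes and with the trended robust variance. The list's median was 2.72, 2.91 and 2.42 on the nuclear arrays and 5.29, 5.04 and 4.04 on cellular replicates 1 to 3, where the seed coat list, at 3.09, 4.29 and 5.11, was highest in replicate 3. Genes of DNA methylation, Polycomb and small RNA pathways fell in 2 of 25 cases and rose in 0 (8 fell when adjusted over the list alone), with a median of -1.06, or -1.19 relative to all genes (camera adjusted p = 3.43e-06; adjusted p = 0.167 with an estimated correlation). The 2 falls were CMT3, a non-CG DNA methyltransferase, at 11.6-fold (SE 0.34, adjusted p = 0.00709) and DCL3, which makes small interfering RNA, at 2.77-fold (SE 0.29, adjusted p = 0.0414), whose call was lost after cyclic loess, after quantile normalization and with the trended robust variance. None of 19 SR splicing factor genes passed, also when adjusted over the list alone, and the median was -0.50, or -0.63 relative to all genes (camera adjusted p = 0.0190; adjusted p = 0.167 with an estimated correlation). In that list 5 genes were lower at an unadjusted p under 0.05, and its medians overlap, at 5.56 on nuclear replicate 1 and 5.54 on cellular replicate 3. The median was -0.18 without nuclear replicate 2 and -0.02 after cyclic loess, where the call was lost (adjusted p = 0.941, against 0.00842 to 0.941 over the alternatives), as it was after quantile normalization and over the brighter genes. The lowest p in that list were those of SR45, with a log2 change of -1.51 (adjusted p = 0.0809), and RSZ22, with -1.31 (adjusted p = 0.112). The mean cellular level of the SR genes was 5.58, close to the 5.55 of the cell cycle genes. Random lists matched on the cellular mean of the cell cycle genes had a median of -0.71. A fall of the SR genes beyond that of genes of their level was therefore not shown.

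Nuclear-encoded photosynthesis genes were higher in nuclear RNA in 16 of 39 cases and lower in 0 (27 rose when adjusted over the list alone). Their median was 1.42, or 1.28 relative to all genes (camera adjusted p = 2.49e-13; adjusted p = 0.167 with an estimated correlation). Besides RBCS1B, the largest rise was that of LHCB2.2, a chlorophyll-binding antenna protein, at 14.4-fold (SE 0.56, adjusted p = 0.0172). Early wound, touch and cold response genes rose in 6 of 23 cases and fell in 0 (6 rose when adjusted over the list alone), with a median of 1.36, or 1.22 relative to all genes (camera adjusted p = 1.79e-06; adjusted p = 0.273 with an estimated correlation). Their median was 0.70 without nuclear replicate 3. RRTF1 and WRKY40, transcription factors induced by stress, were 10.8-fold (SE 0.58, adjusted p = 0.0262) and 10.7-fold (SE 0.57, adjusted p = 0.0244) higher. The photosynthesis median was 5.82, 5.43 and 5.34 on the nuclear arrays and 3.46, 4.02 and 4.47 on the cellular arrays, and the seed coat median 6.63, 5.62 and 5.69 and 3.09, 4.29 and 5.11. The wound response median was 4.01, 3.72 and 5.54 on nuclear replicates 1 to 3 and 3.21, 3.93 and 4.46 on cellular replicates 1 to 3, so these groups overlap: cellular replicate 3 lay above nuclear replicates 1 and 2, and cellular replicate 2 above nuclear replicate 2.

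Seed coat marker genes, which mark a maternal tissue around the embryo, all had a higher nuclear than cellular mean (20 of 20), but 0 passed the limma test, also when adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05. Their median was 1.15, or 1.01 relative to all genes (camera adjusted p = 0.00104; adjusted p = 0.347 with an estimated correlation), 0.61 without cellular replicate 1 and 1.93 without cellular replicate 3. Over the camera alternatives the adjusted p lay between 3.52e-06 and 0.347, the estimated correlation included. The rotation test fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, gave an adjusted p of 0.129. The lowest p were those of AHA10, with a log2 change of 1.85 (SE 0.54, adjusted p = 0.107), and DFR, an enzyme of seed coat tannin synthesis, with 2.35 (SE 0.80, adjusted p = 0.152). Seed storage and oil body genes had a median of 0.60, or 0.47 relative to all genes, with 0 of 9 past the threshold (2 higher at an unadjusted p under 0.05 and 1 that rose when adjusted over the list alone; camera adjusted p = 0.0278; adjusted p = 0.187 with an estimated correlation). CRU3, a cruciferin, had a log2 change of 1.74 (adjusted p = 0.0506) and SESA4, an albumin, 0.87 (adjusted p = 0.186). Leaving out nuclear replicate 1 took that median to 0.92, and the list's call was lost without nuclear replicate 3 (adjusted p = 0.0545), cellular replicate 2 (adjusted p = 0.0553) or cellular replicate 3 (adjusted p = 0.0546). It was also lost after cyclic loess (adjusted p = 0.0723) and quantile normalization (adjusted p = 0.0768), with adjusted p from 0.00642 to 0.187 over all alternatives, the estimated correlation included. Endosperm markers lay near the dim end of all arrays, at medians of 1.74 to 2.07, and did not pass as a list: 0 of 16 passed, also when adjusted over the list alone, and 0 at an unadjusted p under 0.05, with a median of 0.21, or 0.08 relative to all genes (camera adjusted p = 0.320). The median was 0.06 without nuclear replicate 2. The lowest p there were those of MEA, with a log2 change of 0.45, and AGL90, with -0.31.

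**Figure D2:**
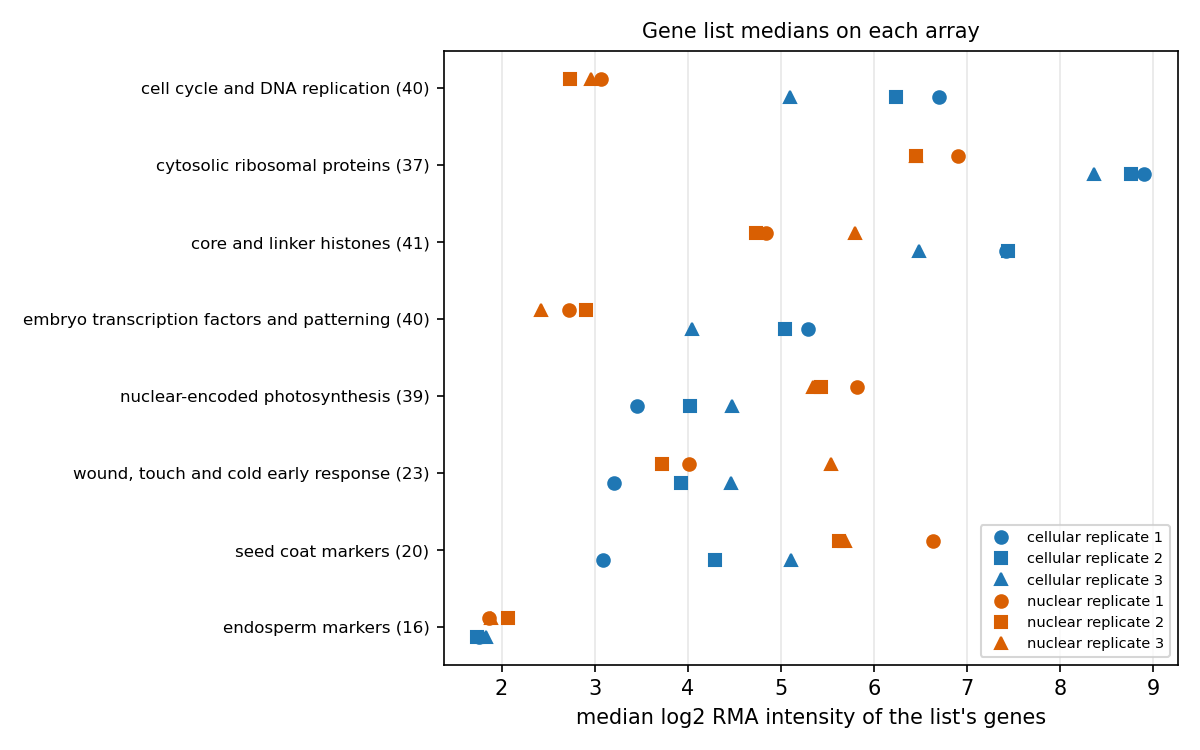
Median log2 RMA intensity of the genes of 8 lists on each of the 6 arrays, with the number of measured genes in brackets. Symbols are arrays, shaped by replicate number and coloured by group, and some coincide; the cell cycle list lies between 5.10 and 6.70 on cellular arrays and between 2.74 and 3.07 on nuclear arrays, and the seed coat list between 3.09 and 5.11 on cellular and between 5.62 and 6.63 on nuclear arrays.

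MicroRNA primary transcripts rose in 3 of 174 cases and fell in 1 (1 rose and 0 fell when adjusted over the list alone). The rises were those of MIR167a at 14.7-fold (SE 0.36, adjusted p = 0.00699), MIR834 at 4.03-fold (SE 0.34, adjusted p = 0.0263) and MIR404 at 1.72-fold (SE 0.17, adjusted p = 0.0493), and the fall was that of MIR413, at 2.86-fold (SE 0.30, adjusted p = 0.0390). The call of MIR404 was lost after centring, with both filters on dim genes and with the trended robust variance. The list median was 0.27, or 0.14 relative to all genes (camera adjusted p = 0.00102; adjusted p = 0.287 with an estimated correlation), and the call was lost after cyclic loess (median 0.06, adjusted p = 0.385) and quantile normalization (adjusted p = 0.180), with adjusted p from 3.18e-05 to 0.385 over the alternatives. Long non-coding and antisense genes rose in 8 of 390 cases and fell in 7 (5 and 5 when adjusted over the list alone), with a median of 0.27, or 0.14 relative to all genes (camera adjusted p = 0.00488; adjusted p = 0.167 with an estimated correlation). The extremes were AT3G58795 (5.75-fold) and AT2G19582 (4.75-fold) among the rises and AT3G59765 (log2 change -4.56) and AT5G44562 (17.7-fold) among the falls. The microRNA list was dim, with medians of 1.78 to 1.98 on nuclear and 1.65 to 1.74 on cellular arrays. So was the long non-coding list, at 2.48 to 2.63 and 2.31 to 2.35. The lower quartile of all genes was also higher on the nuclear arrays, at 1.96 to 2.13 against 1.82 to 1.88. A rise of these lists was therefore not separated from a general shift of dim values. Small nucleolar and spliceosomal RNA genes did not pass as a list (median 0.20, camera adjusted p = 0.480; median 0.09 without nuclear replicate 2 and 0.31 without cellular replicate 2), with 2 rises and 3 falls in 81 (7 and 5 when adjusted over the list alone). AT3G47348 was 6.75-fold and AT3G24615 3.25-fold higher, and AT2G43141 was 10.9-fold, AT4G26365 5.18-fold and AT5G66567 2.40-fold lower. The call of AT2G43141 was lost after cyclic loess and quantile normalization, and that of AT3G24615 with the trended robust variance.

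Auxin response factors and Aux/IAA genes did not pass as a list, with a median of 0.07, a mean of -0.18 and a downward camera statistic (adjusted p = 0.485). The median was -0.03 after centring on protein-coding genes, 0.04 without nuclear replicate 2 and 0.12 without cellular replicate 1. In that list 3 of 44 fell and 0 rose (4 fell when adjusted over the list alone): ARF18 by 4.92-fold (SE 0.46, adjusted p = 0.0404), MP, an auxin response factor of embryo axis formation, by 4.22-fold (SE 0.32, adjusted p = 0.0197), and IAA18 by 3.37-fold (SE 0.37, adjusted p = 0.0480). None of the 3 calls held after cyclic loess, where the log2 changes of ARF18, MP and IAA18 were -1.78, -1.54 and -1.60, and those of ARF18 and MP were also lost after quantile normalization and that of IAA18 with array weights. Heat and protein folding genes had a median of 0.23 with 0 of 16 past the threshold, also when adjusted over the list alone, and 3 higher at an unadjusted p under 0.05 (camera adjusted p = 0.223). That median was 0.37 without nuclear replicate 1, 0.14 without nuclear replicate 3 and 0.15 without cellular replicate 1. HSFA7A had a log2 change of 0.54 and HSFA2 one of 0.53. Respiratory chain genes of the nucleus, found by name alone, had a median of -0.62 with 0 of 8 past the threshold (2 fell when adjusted over the list alone, camera adjusted p = 0.0626). The list passed without nuclear replicate 1 (adjusted p = 0.0441), without nuclear replicate 2 (adjusted p = 0.0483) and with array weights (adjusted p = 0.0425), and had an adjusted p of 0.273 with an estimated correlation, the highest over the camera alternatives. The rotation test fry, which asks another question, gave an adjusted p of 0.0459. COX15, an assembly factor of cytochrome c oxidase with a log2 change of -1.27 (adjusted p = 0.0535), and COX6B, a subunit of that enzyme with -1.02 (adjusted p = 0.0702), came nearest. RANGAP1, whose WPP domain is part of the usual INTACT tag, had a log2 change of -1.43 (SE 0.54, adjusted p = 0.180).

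Organelle-encoded loci have no match in the reference table and were compared over all 27826 rows. Mitochondrial loci fell in 16 of 92 cases and rose in 0, with a median of -0.88, or -1.01 relative to all rows (camera adjusted p = 1.38e-08; adjusted p = 0.288 with an estimated correlation). The list's adjusted p lay between 1.94e-16 and 0.288 over the camera alternatives, and fry gave 0.106. The largest falls were those of ATMG00920 (24.3-fold) and ATMG00810 (15.9-fold). Of the 92 mitochondrial rows 31, and of the 14 chloroplast rows 5, share all 6 values with a nuclear-chromosome row, and the 16 falls, 4 of them such rows, hold 15 distinct sets of values. Without the shared rows, an alternative chosen after seeing the data, 12 of 61 mitochondrial loci fell, with a median of -1.08. Without cellular replicate 2 only ATMG01250 fell and the median was -0.53. Leaving out any other array left 4 to 10 falls, and the replicate block left 5. Cyclic loess left 8 falls and 1 rise, that of ATMG00990, with a median of -0.56. ATMG01250 (10.6-fold), chosen after its values were seen, was the only mitochondrial locus called under every alternative run for these rows, which leaves out the 1.5-fold limit. The call of ATMG00920 was lost with the block and without nuclear replicate 1 or any 1 cellular array. That of ATMG00810 was lost after cyclic loess, after quantile normalization and without any 1 array other than nuclear replicate 3. Chloroplast loci rose in 3 of 14 cases and fell in 0, with a median of 0.31 (camera adjusted p = 0.120) that was 0.63 without nuclear replicate 2, 0.20 without nuclear replicate 3 and 0.07 without cellular replicate 1. That list passed after cyclic loess (median 0.85, adjusted p = 9.55e-05), after quantile normalization (adjusted p = 0.0140), over the brighter genes (adjusted p = 0.0109) and without the shared rows (adjusted p = 0.0420). It also passed without nuclear replicate 2 (adjusted p = 0.0194) and without cellular replicate 2 (adjusted p = 0.0209), with adjusted p from 9.55e-05 to 0.562 over the camera alternatives. ATCG00970 and ATCG01160, which share the same values on every array, were 19.0-fold higher, a call lost without cellular replicate 2, and ATCG00240 was 7.23-fold higher. Of the 49 pseudogenes, 22 share all 6 values with an organelle locus, so nuclear copy and organelle gene cannot be separated there. Within that list AT3G20365 (7.23-fold, identical to ATCG00240) and AT2G07600 (3.94-fold) were higher. AT2G07683 (9.51-fold), AT2G07826 (7.61-fold, identical to ATMG01210), AT2G07697 (5.52-fold) and AT2G07686 (5.33-fold, identical to ATMG00750) were lower. Of 35 nuclear-chromosome rows identical to an organelle row, 32 lie on the AT2G07 stretch of chromosome 2. AT2G07600, AT2G07683 and AT2G07697 lie there too without identical values, and whether organelle RNA adds to their signal was not tested. The pseudogene list had a median of -0.22, which became 0.08 after cyclic loess (camera adjusted p = 0.0685; 2 rose and 5 fell when adjusted over the list alone). It passed without nuclear replicate 3 (median -0.31, adjusted p = 0.0373), without cellular replicate 1 (median -0.55, adjusted p = 2.53e-04), with the trended robust variance (adjusted p = 0.0443) and with camera on ranks (adjusted p = 0.0341), while its median was -0.06 without cellular replicate 3, with adjusted p from 2.53e-04 to 0.825 over the alternatives.

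Across genes, which are not independent replicates, the nuclear and cellular group means correlated with a Pearson r of 0.819 and a Spearman rho of 0.840. Single arrays correlated between 0.887 and 0.931 within the cellular group, between 0.829 and 0.844 within the nuclear group and between 0.688 and 0.824 across groups. The first principal component held 54.7% of the variance and separated the groups: the nuclear arrays lay at -83.9, -83.6 and -69.8 and the cellular arrays at 107.4, 89.0 and 40.9. Cellular replicate 3 was the cellular array nearest to the nuclear ones. Its correlation with each nuclear array, 0.803, 0.793 and 0.824, was higher than that of the other cellular arrays. The median SD of a gene on the log2 scale was 0.343 in the nuclear and 0.267 in the cellular group. Of 69 named genes past the threshold, 46 lost the call without cellular replicate 2, 38 without cellular replicate 1, 28 without nuclear replicate 2, 25 without nuclear replicate 1, 19 without nuclear replicate 3 and 7 without cellular replicate 3. The 23 that held under every alternative but the 1.5-fold limit, where single genes were not followed, include CYCB1;4, HTA8, AT3G53650, CMT3, RPL23AB, MIR167a, AT4G26365, AT3G59765, AT3G20365, AT2G07683 and AT2G07697.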

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

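Quantile normalization, identical rows counted once, shared organelle rows left out and the ribosomal lists by rule alone were chosen after the results were seen. The counts of genes higher in nuclear RNA, genes lower in nuclear RNA, genes at least 2-fold higher in nuclear RNA and genes at least 2-fold lower in nuclear RNA stayed within 1.5 times those reported under centring, both filters, the trended robust variance, array weights, all rows, quantile normalization and identical rows counted once. Cyclic loess gave 489 higher and 846 lower genes, 481 and 830 of them at least 2-fold, and 282 higher and 812 lower genes were the same as without it; the cause was not tested. A 1.5-fold limit inside the test left 73 higher and 535 lower genes, by its construction. With the replicate number as a block, 118 genes were higher and 571 lower, all at least 2-fold, and 93 and 543 were the same genes. Residuals of same-numbered arrays correlated at -0.053, -0.057 and -0.012, none correlated best with its own number, and the numbers were not taken to pair samples. Leaving out each array in turn gave, with fewer samples, 28 to 419 higher and 254 to 1688 lower genes, and 28 to 419 and 254 to 1687 at least 2-fold. The correlation of nuclear and cellular group means was 0.670 over genes brighter than the median, which narrows the range of values, and otherwise moved by less than the spread between arrays. The gene lists past the threshold numbered 0 with an estimated inter-gene correlation, which widens the test's error, 9 to 14 with the other camera settings and 13 with fry, which compares a list with no other genes.

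The list median of translation elongation and initiation factors changed sign after cyclic loess (0.0692), that of pseudogenes and transposable element genes after cyclic loess (0.07725), and that of auxin response ARF and Aux/IAA genes after centring (-0.03079) and over brighter genes (-0.05038). The median of nuclear-encoded organellar ribosomal proteins became 0.3497 after cyclic loess and 0.2847 after quantile normalization, and lay between -0.1284 and 0.08824 with single arrays left out. The cause of these sign changes was not tested. Of 69 named genes past the threshold, 23 passed under all settings but the 1.5-fold limit, where single genes were not followed. The call was lost for 8 after cyclic loess and for 27 with the block. The mean of a gene's rows was not run, since each gene has 1 row. Signal over background limits the folds of dim genes.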

Other observations

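The test of dilution, quantile normalization, the groupings by symbol and by gene length and the matched lists for the EIF group were chosen only after the result was seen, and the 3 marker lists were written after the first results but before their own values. Genes were also grouped by shared symbol or synonym, and camera with the preset correlation was run on each group. Genes with a synonym calling them embryo defective, needed for embryo development, fell in 33 of 259 cases and rose in 0, with a median log2 change of -0.51 (camera adjusted p = 1.75e-10; adjusted p = 0.431 with an estimated correlation). Translation initiation factor genes named EIF, some of them also in the list of translation factors, fell in 10 of 21 cases and rose in 0, with a median of -1.80 (camera adjusted p = 1.18e-09; adjusted p = 0.431 with an estimated correlation). Genes of RNA polymerase II and related subunits named NRPB fell in 4 of 15 cases, namely NRPB10, NRPB6B, NRPB11 and NRPB4, and rose in 0 (median -1.67, camera adjusted p = 2.31e-06; adjusted p = 0.431 with an estimated correlation). KCS genes, which elongate very long chain fatty acids, rose in 2 of 21 cases, KCS5 and KCS6, and fell in 0 (median 0.63, camera adjusted p = 0.0187; adjusted p = 0.431 with an estimated correlation). These directions held after cyclic loess, with medians of -0.44, -1.39, -1.34 and 0.48. In the fit over the 14206 genes brighter than the median, 417 were higher and 1659 lower, so falls were common among bright genes. Random lists of matched level were not drawn for the embryo defective, NRPB and KCS groups. A shift shared by genes of their level was therefore not separated there. In all, 37 of 175 such groups passed with the preset correlation and 0 with an estimated one.

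The 3 marker lists written later are described here in turn. Calvin cycle and photorespiration genes rose in 5 of 19 cases and fell in 0: GLDP1, SBPASE, GAPB, HPR and CA2, at 9.32-fold, 5.50-fold, 5.01-fold, 4.43-fold and 2.65-fold, the call of CA2 being lost with the trended robust variance (median of the list 1.16, camera adjusted p = 1.77e-07; adjusted p = 0.0933 with an estimated correlation). In a second integument and seed coat list 1 of 13 rose, CESA5, with a log2 change of 1.86, and 9 of 13 lay above 0, the call of CESA5 being lost after quantile normalization and with the trended robust variance (median 1.00, camera adjusted p = 0.0770, so the list did not pass; adjusted p = 0.436 with an estimated correlation). Vascular and guard cell genes were dim, with 0 of 12 past the threshold and a median of 0.47 (camera adjusted p = 0.0223; adjusted p = 0.0933 with an estimated correlation).

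The first pattern weighed is that the median changes of the photosynthesis and seed coat lists lay above and those of the cell cycle and embryo patterning lists below that of all genes, while the endosperm markers, dim on all arrays, lay at the 65.61st percentile of matched random lists (median 0.21 against 0.18, and 0.06 without nuclear replicate 2). A narrower distribution of the nuclear arrays is argued against: with all arrays given one distribution the cell cycle median stayed at -2.38 relative to all genes, its quartiles at -3.16 and -1.44. RNA of integument or seed coat in the nuclear samples may contribute, since the second seed coat list's median lay at the 99.95th percentile of 10000 random lists matched on mean expression. Yet 1 of its 13 genes and 0 of the 20 of the first list passed, and the camera adjusted p of the second list was 0.0770. RNA of other green tissue may contribute too, since the Calvin cycle list lay at the 100th percentile. Both percentiles come from lists drawn gene by gene, while the first seed coat list had an estimated inter-gene correlation of 0.393. They may therefore overstate the departure. Camera with an estimated correlation gave adjusted p of 0.436 for the second seed coat list and 0.0933 for the Calvin cycle list. The abundant TT4, LDOX and MYB5 had nuclear means of 10.06, 9.79 and 8.76 and cellular means of 8.44, 8.69 and 5.06, and AGT of the Calvin cycle list means of 7.76 and 6.63. None of these genes passed the limma test (adjusted p = 0.274, 0.378, 0.0945 and 0.126). Nuclear replicate 2 lay below cellular replicate 3 for TT4 (9.51 and 9.96) and LDOX (9.06 and 9.77). In the second list 9 of 13 genes lay above 0, and MUM4 went the other way, with means of 5.49 and 5.74. Of the 13 and 19 genes, 0 are in another list, and 10 and 13 lie above the median gene in the cellular embryos too; selection of tagged nuclei or hand dissection would remove such RNA if complete. A difference between nuclear and cytoplasmic RNA, which the design names, stays open and untested, because compartment and isolation method change together.

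The second pattern is the lower level of cytosolic ribosomal protein genes. Whether a loss of signal shared by all genes of the same cellular level is the whole cause was not settled. The list's median of -1.76 lay at the 1.25th percentile of random lists matched on the cellular mean, whose own median was -1.08 and 5th percentile -1.595. Those lists were drawn gene by gene, while the ribosomal genes had an estimated correlation of 0.098, so the percentile may overstate the departure. Camera with an estimated correlation gave an adjusted p of 0.131. Matched in the same way, the translation factor list, fixed before the data were examined, lay at the 84.57th percentile, with a median of -0.46. The EIF group lay at the 0.77th, with a median of -1.80. It was taken from the 175 symbol groups after its fall was seen, so its percentile restates that fall and is not separate support. Dilution by RNA of other tissue cannot be told apart from a nuclear and cytoplasmic difference: the ribosomal median lay 0.839 above the cell cycle median (a test chosen after both were seen), which dilution allows, and the level of these genes in any other tissue was not measured here. A compartment difference therefore stays possible and untested.

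The third pattern is that cellular replicate 3 lay nearer the nuclear arrays than cellular replicates 1 and 2. Noise that is independent from array to array is argued against, since replicate 3 minus replicate 1 correlated at 0.377 across genes with the nuclear mean minus replicate 2, which share no array. Replicate 2 minus replicate 1 correlated at 0.02 with the nuclear mean minus replicate 3. That value is no negative control, since replicate 2 also correlated better than replicate 1 with each nuclear array (0.74, 0.73 and 0.77 against 0.69, 0.69 and 0.72). A technical factor shared with the nuclear arrays, or one shared by cellular replicates 1 and 2 alone, could give the same correlation and was not tested. The SD of log2 values was 1.7404, 1.7479 and 1.6859 on cellular replicates 1 to 3 and between 1.415 and 1.5955 on the nuclear arrays. A larger share of seed coat RNA in cellular replicate 3 is a candidate explanation: the second seed coat list lay 0.88 higher there than in the mean of replicates 1 and 2, at the 99.95th percentile of matched random lists. Its median was 2.63, 3.98 and 4.69 on cellular replicates 1 to 3, and TT4 of the first list was at 6.78, 8.59 and 9.96. Replicate 2 thus also lay above replicate 1. In the same contrast the photosynthesis list moved by 0.56, and the cell cycle, embryo patterning and ribosomal lists by -1.17, -0.58 and -0.36. The first seed coat list had been seen to differ before the test of the second was set. The random lists were drawn gene by gene and the contrast rests on a single array, so the percentile may overstate the departure. The share of seed coat RNA itself was not measured, and no other biological explanation was tested.

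Of the 10 ways to split the 6 arrays into 3 and 3, 1, the real one, gave as many genes past the threshold either way (1597), higher (313), lower (1284), and at least 2-fold higher (297) or lower (1273), and the highest of the other splits gave 0 for each. For lists past the threshold (13 in the real split) 2 of the 10 gave as many, the highest of the others being 13, from the split of nuclear replicate 1 with cellular replicates 1 and 2 against the rest. With 10 splits no share under 0.05 can be reached. Each other split puts arrays of both groups on each side, so the group difference widens the residual spread and few calls could arise. The 0 is therefore no measure of what unrelated arrays would give.

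With protein-coding genes ordered by length into 5 groups, the median log2 change was 0.23 in the shortest group (median length 826 bp; 61 rose and 118 fell) and -0.02 in the longest (4263 bp; 65 rose and 340 fell). The median level was 1.14 higher on the log2 scale in the longest than in the shortest group, so length and brightness were not separated.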
